A study of Mus musculus with 8 samples.

How the data were processed

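Polyadenylated mouse RNA from MII oocytes, blastocysts and implantation sites of connexin 43 KO and WT origin was measured on 8 Affymetrix arrays. The authors deposited a table of signal intensity for all arrays, made with MAS5 according to the submitters' processing notes, where the version is not given in the sources used here. The intensity is on a linear scale, and the 2% trimmed mean over all probe sets was 500 on every array, which was tested on the values. No further normalization between arrays was found in the table, and no detection calls are in it, so background was read from the Bacillus control probe sets of each array. This assumes that no Bacillus RNA was added to the samples, which the sources used here do not state. The brightest of these 15 probe sets is a strict level: it read 100 to 560, against medians of 18.5 to 123. For arrays, depth has no count, and the number of arrays limits the precision. Samples were grouped by stage and genotype as the labels give them: 1 array each for oocyte KO, oocyte WT, implantation site KO and implantation site WT, and 2 each for blastocyst KO and WT.

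Of 45101 probe sets, 34945 were annotated to a single gene by the platform table, with symbols updated through the RefSeq gene table of GRCm38, giving 18193 genes. Probe sets annotated to several genes (932) or none (9160) and 64 control probe sets were left out of the gene tests. Each gene was represented by the probe set with the highest mean log2 signal over the 8 arrays. Probe sets in the upper 50% by that mean (22519, a mean signal of at least 151) were kept, leaving 11746 genes. The filter, the gene lists, the tests and the alternatives were fixed before the data were examined, except where stated.

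Blastocyst KO and WT were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). A KO effect common to the stages, and the stage differences, came from a second limma fit over all 8 arrays with stage and genotype as terms. Differences between stages in the KO effect were not tested, since oocytes and implantation sites have 1 array per genotype. Oocytes and implantation sites, with 1 array per genotype, were described by the log2 difference and by counts of genes at least 2-fold apart. For these, the median of each gene list was set among 10000 random lists of equal size matched on mean signal over the 8 arrays in 20 bins, as a description and not as a test. A set of 30 gene lists covered ribosome and translation, energy, cell cycle and stress, lineage markers of oocyte, blastocyst and uterus, and other cell types the samples could hold, and 29 lists with at least 5 measured genes were tested with camera of limma at a preset correlation of 0.01 and again with an estimated correlation. Of 939 listed genes 833 had a probe set. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

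Named genes were chosen by rule: Gja1, and in each tested comparison the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05 whose groups did not overlap, filled where fewer passed by the largest non-overlapping changes at an unadjusted p under 0.05, said not to pass. In oocytes and implantation sites they were the 10 largest differences in each direction, and from each list up to 4 members with the largest absolute difference. Genes with only a clone or model name were counted and not named. The naming with a pseudocount of 61.8 in the unreplicated stages was added after the values were seen.

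The alternatives were quantile normalization, scaling to a common median, the pseudocount, no filter, the upper 30% of probe sets, the mean of all probe sets of a gene, probe sets without suffix only, limma without the trend, the replicate number as a block, an estimated set correlation and leaving out each array or stage in turn. Adding 387 probe sets shared with pseudogenes was chosen after the data were seen. Replicate numbers 1 and 2 do not pair KO with WT in the labels, and across 11746 genes, which are not independent replicates, the difference between the KO arrays had a correlation of 0.0182 with that between the WT arrays.

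The fits were tested on simulated data with the same genes and spread. With 67, 67 and 66 genes changed 2, 4 and 8-fold, the blastocyst fit called 0%, 10.4% and 47.0% of them and 0 unchanged genes, and the fit over the stages 2.99%, 35.8% and 66.7% with 5 unchanged genes. A shift of -0.5 put into the ribosome biogenesis list was called in both fits, with 0 and 1 other lists called. The simulated noise was independent between genes, whereas the estimated correlation of translation factors, for example, was 0.40 in blastocysts. The simulation therefore does not show how often lists are wrongly called at the preset correlation.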

Results

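Gene expression was measured on 8 Affymetrix mouse arrays, each reading 45101 probe sets from polyadenylated RNA. The samples came from 3 stages, mature (MII) oocytes, blastocysts and implantation sites, and from 2 genotypes, a knockout (KO) of connexin 43, the gap junction protein encoded by Gja1, and wild type (WT). The series design asks how loss of connexin 43 affects the transcriptome at each stage, and its title links the loss to ribosomal and translational genes. Oocytes and implantation sites had 1 array per genotype, so no replicate check of those differences exists and only sizes are given for them. Blastocysts had 2 arrays per genotype, and this number limits the precision of every test. Nothing in the labels says that the replicates came from separate cultures or animals, in which case the p-values measure only the spread between these arrays. The 2% trimmed mean was 500 on every array, and the median signal ranged from 134 on the implantation site KO array to 220 on the first blastocyst KO array.

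Gja1 (gene identifier 14609), which lies on chromosome 10 of the mouse assembly GRCm38.p6 (56377300 to 56390419), was bright on the first blastocyst WT array and at the implantation site, and lower on the KO arrays of both stages. In blastocysts, the probe set that represents the gene read 375 and 553 on the KO arrays, 9835 on the first WT array and 574 on the array labelled WT replicate 2, a signal close to those of the KO. The KO values were below the brightest Bacillus control probe sets of the same arrays (395 and 560), taken here as the level of background. A pair of the 6 Gja1 probe sets exceeded that level on the first KO array (516 and 412). On the array labelled WT replicate 2 the brightest control was 219, so that 574 was above that level there. Of the other Gja1 probe sets on that array, those at 190 and 166 lay below that level and those at 242, 430 and 855 above it. Among these others, only the 855 exceeded the same probe set on both KO arrays (516 and 535). At the implantation site the representing probe set read 28105 in the KO and 44493 in the WT, 1.58-fold lower in the KO. The other bright probe sets of the gene were 1.55 to 3.90-fold lower, while a dimmer probe set read 599 in the KO and 412 in the WT. In oocytes the representing probe set read 150 in the KO and 126 in the WT, below the brightest Bacillus controls at 334 and 132, and another probe set was above them on each array (353 in the KO, 139 in the WT). The blastocyst difference was -2.38 on the log2 scale (SE 1.06) and did not pass (adjusted p = 0.332, limma), but it was -4.43 and passed without the array labelled WT replicate 2, and -0.33 without the first WT array. The labels do not say which part of the transcript was deleted or where the probe sets lie, and the remaining signal at the implantation site was not assigned to a cell type or transcript.

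**Figure D1:**
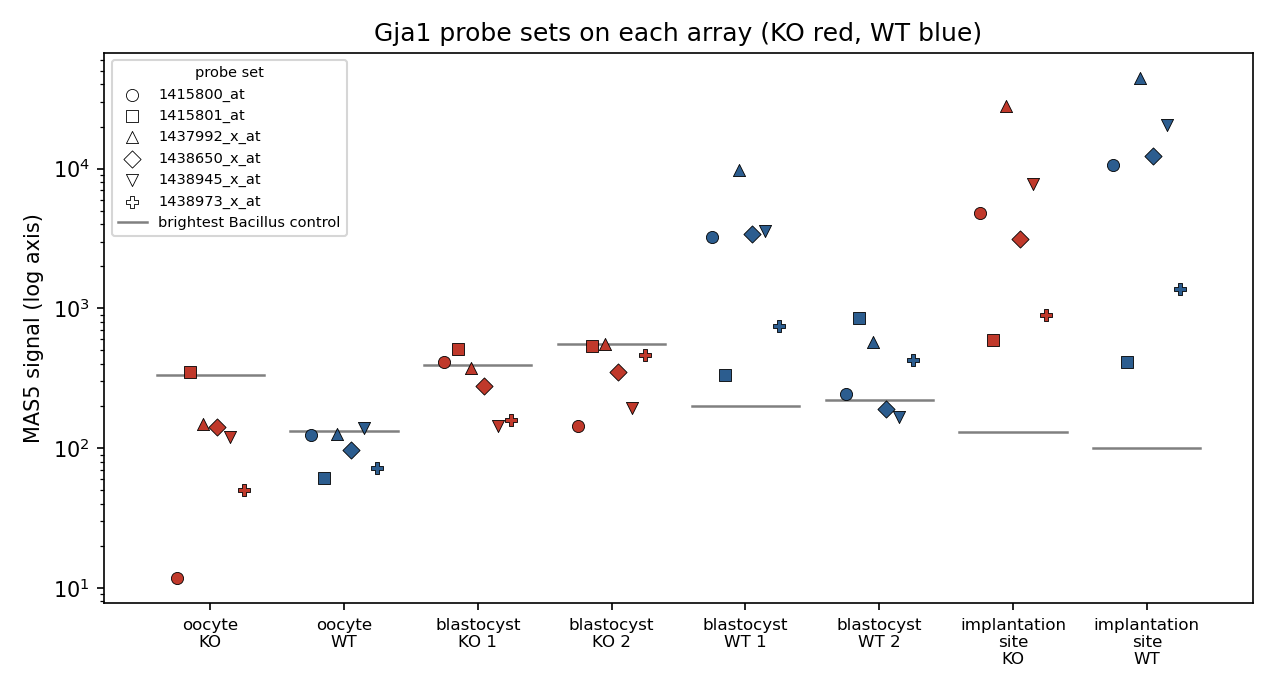
MAS5 signal (log axis) of the 6 Gja1 probe sets on each of the 8 arrays, with KO arrays in red, WT arrays in blue, a symbol per probe set and a grey line at the brightest Bacillus control of that array. The representing probe set reads 9835 on the first blastocyst WT array and 574 on the array labelled WT replicate 2.

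In KO blastocysts, 12 of 11746 genes tested were higher than in WT and 0 were lower. The largest rise among named genes was that of Acap1, a GTPase-activating protein of endosomal recycling, which read 5270 and 6031 in the KO against 256 and 189 in the WT, a 25.6-fold difference (log2 4.68, SE 0.35, adjusted p = 0.00727). Developmental regulators were among the 12: the homeobox gene Hoxc6 rose 19.9-fold (log2 4.31, SE 0.54), the homeobox gene Gsc2 8.56-fold (3.10, SE 0.33) and Smo, the signal transducer of the Hedgehog pathway, 10.1-fold (3.33, SE 0.33). Nova2, a splicing regulator best known from neurons, rose 19.9-fold (4.31, SE 0.44), and Ankzf1, which acts in ribosome-associated quality control, 12.4-fold (3.63, SE 0.42). The lipoxygenase Aloxe3 rose 11.1-fold (3.47, SE 0.40), the water channel Aqp11 9.70-fold (3.28, SE 0.28), the ubiquitin ligase Ttc3 9.66-fold (3.27, SE 0.42) and the lipid-binding protein Sec14l3 6.63-fold (2.73, SE 0.35). Adjusted p of these 10 lay between 0.00727 and 0.0449. Nova2 on both WT arrays (170 and 199), Acap1 on the array labelled WT replicate 2 and Ankzf1 on the first WT array (191) were below the brightest Bacillus control, so their folds are approximate (log2 3.92, 4.34 and 3.34 with a pseudocount). Acap1 lies on chromosome 11 (69881566 to 69895568), Hoxc6 on chromosome 15 (102998226 to 103011882), Nova2 on chromosome 7 (18925888 to 18965319) and Smo on chromosome 6 (29735497 to 29761366). The other 2 were Zfp420 (log2 2.49), named after its value was seen, and a transcript with only a clone name.

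Other probe sets of the same genes did not always follow. Of the 12 genes, 4 had another probe set bright enough for the filter, and these differed by 2.67 for Hoxc6, 0.20 for Smo, -0.02 for Aqp11 and between -1.11 and 3.00 for the 4 of Ttc3 (log2). Among genes that were lower in the KO, none passed. Of the 10 named without a pass, Nme1 (-3.54, SE 1.11, adjusted p = 0.225) was bright on the first WT array alone at 38645. The stem cell factor receptor Kit (15.3 and 4.45 against 132 and 134, adjusted p = 0.282) and Chd9 were below the brightest Bacillus control on all 4 arrays, and their values of -4.01 and -3.57 shrank to -1.44 each with a pseudocount. Reck, Atp9b, Fam234b, Hivep1, Coq6, Hyi and Usp28 were below it on both KO arrays, so their sizes are not given. By limma with an unadjusted p under 0.05, 1030 genes were higher and 788 lower. The higher calls were 0 with the mean of all probe sets of a gene (921 higher and 570 lower unadjusted) or without the intensity trend (974 and 469), 5 with probe sets without suffix, 23 with a pseudocount, 34 in the brightest 30% of probe sets, 74 higher and 10 lower (88.1% higher) with scaling to a common median, and 91 higher and 1 lower with the replicate number as a block. Without each array in turn they were 23, 13, 3 (first WT array left out) and 294 higher (the array labelled WT replicate 2 left out), with 0, 1, 1 and 22 lower.

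**Figure D2:**
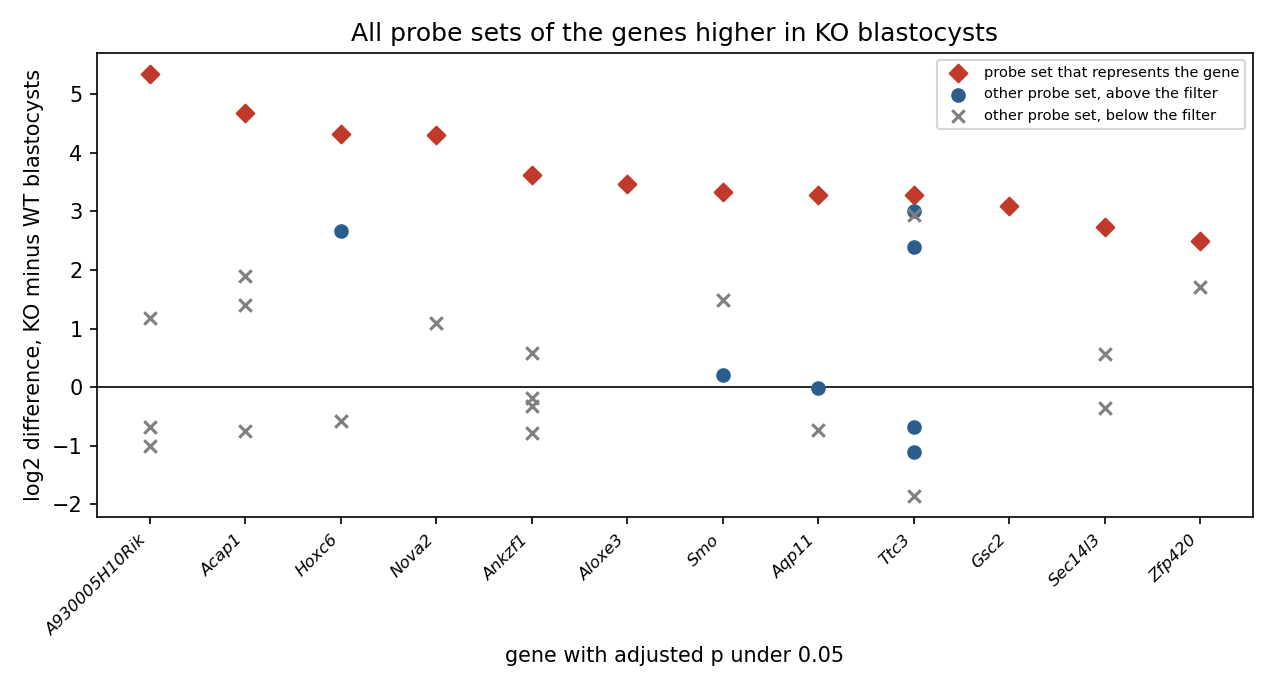
Log2 difference between KO and WT blastocysts (2 arrays per genotype) for every probe set of the 12 genes with an adjusted p under 0.05. Diamonds mark the probe set that represents the gene, blue circles the other probe sets above the filter and crosses those below it. Hoxc6 has another probe set at 2.67, while those of Smo and Aqp11 lie at 0.20 and -0.02.

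Groups of housekeeping genes were lower in KO blastocysts by small amounts, and no member of any list passed on its own over all genes. The 3044 brightest genes were lower as a whole too (median -0.31). Among random lists matched on brightness, translation factors (10.03% of random lists below), ribosome biogenesis (13.5%) and oxidative phosphorylation (52.4%) did not stand out. Their calls below therefore do not separate a housekeeping effect from that shift of bright genes. Mitochondrial ribosomal proteins lay just inside the central 95% (2.83%), and ribosomal proteins were less low than most (99.8%). Of 29 lists tested, 9 were lower and 1 higher with a preset correlation between genes (camera of limma), and with an estimated correlation 0 were (smallest adjusted p = 0.709 with an estimated correlation). Translation factors came first, with 34 of 42 measured members lower and a median of -0.39 (adjusted p = 0.000913). Examples are the initiation factor subunits Eif2b1 (-1.53, SE 0.69), Eif3m (-1.21, SE 0.40) and Eif3b (-1.03, SE 0.38) and the termination factor Gspt1 (-1.22, SE 0.46). Ribosome biogenesis genes were lower too (46 of 64, median -0.29, adjusted p = 0.00457), among them Polr1b, a subunit of the polymerase that transcribes ribosomal RNA (-2.71, SE 0.72), and Noc3l (-2.39, SE 0.58), both below the brightest Bacillus control on the KO arrays. Ribosomal proteins themselves did not pass: 30 of 44 were lower with a median of -0.13 (adjusted p = 0.383), and Rpl37 was higher (2.38, SE 0.33). The ribosomal and translation lists were prompted by the series title, so they are not independent evidence of its direction. Mitochondrial ribosomal proteins were lower in 49 of 74 cases (median -0.29, adjusted p = 0.0476) and oxidative phosphorylation genes in 58 of 69 (median -0.28, adjusted p = 0.00564), with Atp5b at -1.22 (SE 0.38). Single arrays moved these medians. Without the first KO array 0 lists passed as lower, with -0.15 for mitochondrial ribosomal proteins, -0.30 for translation factors and -0.04 for ribosomal proteins. Without the second KO array the ribosomal median was -0.23. Without the first WT array the medians were -0.15 for translation factors, -0.16 for mitochondrial ribosomal proteins and -0.11 for oxidative phosphorylation, none passing, ribosome biogenesis genes did not pass either (-0.20), and the ribosomal median turned to 0.06. Without the array labelled WT replicate 2 the medians were -0.63 for translation factors and -0.50 for oxidative phosphorylation, and ribosomal proteins passed as lower at -0.42. Members that passed when adjusted over the list alone numbered 1 higher for ribosomal proteins (Rpl37), 2 higher for mitochondrial ribosomal proteins, and 0 for translation factors, ribosome biogenesis and oxidative phosphorylation.

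Lists of pluripotency and chromatin genes were lower as well, with the preset correlation only. None of the list calls that follow held otherwise (adjusted p = 0.709 or above with an estimated correlation). Inner cell mass markers had 13 of 16 members lower (median -0.44, adjusted p = 0.0405), including Klf4 (-1.14, SE 0.34), Fgf4 (-1.03, SE 0.43) and Sall4 (-0.93, SE 0.29). Epigenetic regulators had 19 of 22 lower (median -0.51, adjusted p = 0.00274), led by the 5-methylcytosine dioxygenase Tet1 (-1.72, SE 0.34) and by Uhrf1, which recruits maintenance methylation (-1.10, SE 0.32). Cell cycle genes (25 of 35 lower, adjusted p = 0.0393; Ccnd3 -2.01, SE 0.52, at control level in the KO), stress response genes (17 of 27, adjusted p = 0.0393; the heat shock gene Hspa1b -1.93, SE 0.42) and proteasome genes (24 of 31, adjusted p = 0.0405; Psma1 -1.11, SE 0.29) completed the lower lists. Without the first WT array the medians were -0.28 for inner cell mass, -0.17 for stress response and 0.00 for proteasome genes, none passing, while without the array labelled WT replicate 2 those of cell cycle, stress response and proteasome genes were -0.56, -0.83 and -0.54. Inner cell mass markers did not pass without the second KO array either. Immune and blood markers were the list called higher (9 of 13 higher, median 0.97, adjusted p = 0.0405, or 0.709 with an estimated correlation), with the myeloid genes Csf1r (5.64-fold, SE 0.75 on the log2 scale) and Tyrobp (3.61-fold, SE 0.48). Its median signal on the KO arrays (312 and 319) was below the brightest Bacillus controls there (395 and 560), and the call was lost after quantile normalization, without the filter, in the brightest 30% of probe sets and without either KO array or the first WT array (0 lists higher in each). Without the array labelled WT replicate 2 it passed with a median of 0.46. Adjusted over the list alone, 1 member of the stress list and 1 of the epigenetic list were lower, and 0 members of the inner cell mass, cell cycle, proteasome and immune lists passed. Trophectoderm (adjusted p = 0.433), gap junction (0.347) and uterine (0.433) lists, and the other 15 besides the ribosomal proteins, did not pass. In the KO, the 3044 brightest genes had a median of -0.31 and the dimmer 5873 genes one of 0.27, and the 3' to 5' signal ratio of the Actb control was 25.7 and 39.0 against 69.3 and 69.1 in the WT, while that of Gapdh went the other way (11.2 and 11.8 against 7.27 and 7.71). Against random lists matched on brightness, the medians of translation factors (10.03% of random lists below), ribosome biogenesis (13.5%), cell cycle (13.1%), oxidative phosphorylation (52.4%) and proteasome genes (69.2%) did not stand out. Ribosomal proteins were less low than most (99.8%). Stress response genes (0.21%), gap junction genes (0.63%, 7 measured), epigenetic regulators (1.03%) and inner cell mass markers (2.13%) lay below the central 95%. Mitochondrial ribosomal proteins lay just inside it (2.83%) and immune markers above it (99.4%). After quantile normalization 2 of the 9 lower lists, translation factors and epigenetic regulators, still passed, and the lower calls numbered 2 in the brightest 30% of probe sets, 0 without the first KO array and 1, epigenetic regulators, without the first WT array.

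On the oocyte arrays, ribosomal protein genes were lower in the KO, with 38 of 44 below WT, 21 of them at least 2-fold, and a median of -0.88. Rpl27 read 262 in the KO against 1187 in the WT (4.52-fold lower), Rps19 161 against 699 (4.34-fold) and Rps4x 725 against 2764 (3.81-fold), where the KO values of Rpl27 and Rps19 were below the brightest Bacillus control (334). Lists of the same size and brightness had a median of -0.50, and 0% of 10000 such lists lay below the ribosomal one. This list was prompted by the series title, so it is not independent evidence of its direction. With only the probe sets whose name carries no suffix for shared transcripts, 21 ribosomal genes remained and their median was -0.33, with 16.6% of random lists below it. Cumulus and granulosa cell genes had a median of -0.78 (0.03% of random lists below), mixed in direction: Hsd3b1 read 75.1 in the KO against 881 and the activin subunit Inhba 596 against 65.1, both at control level on the dim side. Without the filter and with the mean of all probe sets of a gene, this median turned above 0. Genes of the p53 and apoptosis list had a median of -0.66 (0.36%). Genes of early zygotic activation had higher values in 5 of 5 cases (median 1.53; Duxf3 513 against 177), although Pramel6 and Pramel7 were below the brightest controls on both arrays. With 95.9% of random lists below, that median lay inside the central 95%. Translation factors (-0.35) and ribosome biogenesis genes (-0.19) lay near their random lists, with 61.4% and 50.0% below. With a common median, these were -0.76 and -0.60, the cumulus median -1.19 and that of the p53 list -1.07, which was -0.35 after quantile normalization. Oocyte-specific genes had a median of -0.36 that turned to 0.35 after quantile normalization, and mitochondrial ribosomal proteins one of 0.17 that turned to -0.10.

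In single genes, 2809 were at least 2-fold higher and 1444 at least 2-fold lower on the oocyte KO array, against 2055 genes 2-fold apart between the KO blastocyst replicates and 2952 between the WT ones. The direction of that split followed the scaling: 66.0% of these genes were higher in the KO as deposited, 44.9% after quantile normalization (1803 higher, 2211 lower) and 39.7% with a common median (1892 and 2877), which moved the median of all genes by -0.12 and -0.41. All 20 genes named by size alone, from Rflnb (597 against 9.98) to Dph6 (151 against 4748), lay at the level of the Bacillus controls on their dim side, as did 60.9% of the genes 2-fold apart. With a pseudocount of 61.8, a choice made after the values were seen, the genes above that level on both arrays were Adarb1, an RNA-editing adenosine deaminase (3026 in the KO against 199), the immediate early gene Fos (615 against 6868) and the chaperonin subunit Cct6a (358 against 2718). The 3' to 5' ratio was 6.68 on the KO array and 33.4 on the WT array for Actb and 2.41 and 10.1 for Gapdh, and the 3044 brightest genes had a median of -0.37 against 0.51 for the dimmer 5873.

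The implantation site arrays differed less. On the KO array 719 genes were at least 2-fold higher and 1862 at least 2-fold lower, together 22.0% of genes, a share between those of the KO (17.5%) and WT (25.1%) blastocyst replicates. The neutrophil protein S100a8 read 8258 in the KO against 1209 in the WT and angiogenin (Ang) 2388 against 345. Ggt5, a gamma-glutamyl transferase, read 291 against 3793, and the Mediator subunit Med18 433 against 3654. The importin Kpnb1 read 34032 against 7613 on its brightest probe set, but its difference was -0.33 as the mean of its probe sets. These genes came from the naming with a pseudocount, since all 20 named by size alone, from Ccdc87 (236 against 5.36) to Anapc11 (7.81 against 619), were at control level on the dim side. Oxidative phosphorylation genes had 50 of 69 members higher in the KO (median 0.37, with 99.6% of random lists below), a median of 0.12 after quantile normalization and 0.61 with a common median. Cell cycle genes had 21 of 35 (median 0.34, 99.1%; 0.58 with a common median), but a median of -0.02 with the mean of all probe sets and -0.04 with probe sets without suffix. Ribosomal proteins were higher in 37 of 44 cases, with a median of 0.32 that did not stand out (60.3%), and that was 0.07 with 19 of 44 lower after quantile normalization and 0.56 with a common median. Inner cell mass markers had 14 of 16 lower (median -0.65, 1.56%; -0.29 after quantile normalization and -0.42 with a common median), at median signals of 72.1 and 108 against a brightest control of 131 and 100. Uterine and decidual genes had a median of 0.04, which turned to -0.13 after quantile normalization. The share of 2-fold genes that were higher was 27.9% as deposited, 43.1% after quantile normalization (881 and 1164) and 46.1% with a common median (1169 and 1365), which moved the median of all genes by 0.24. The 3044 brightest genes had a median of 0.16 and the dimmer 5873 one of -0.34, the reverse of oocytes and blastocysts.

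**Figure D3:**
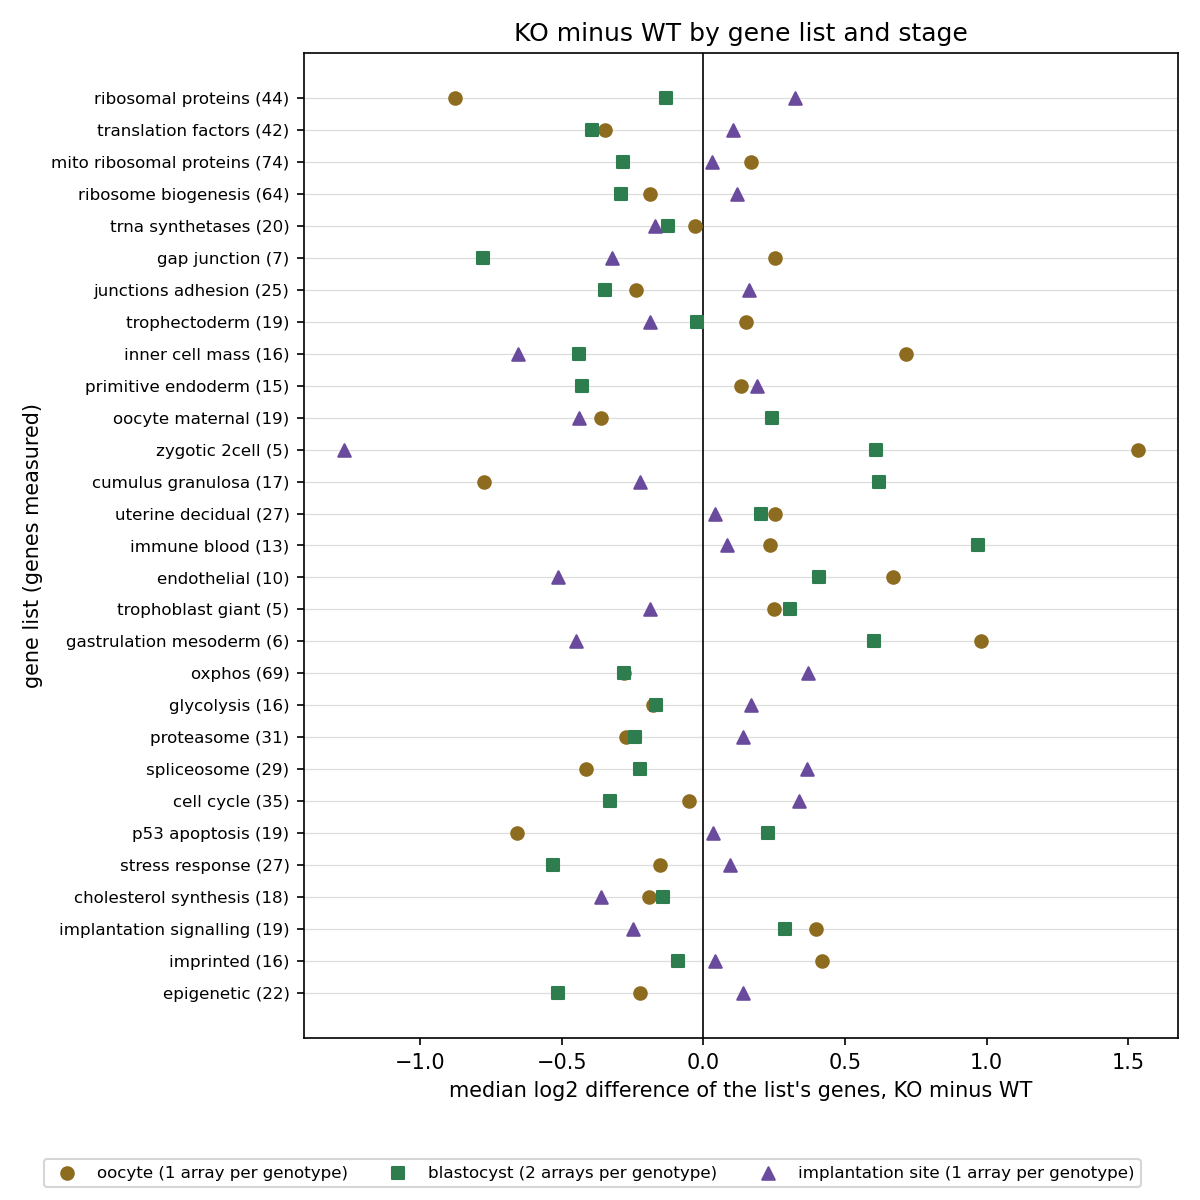
Median log2 difference between KO and WT (horizontal axis) of the genes in each list, with the number of genes measured in brackets, for oocytes (circles, 1 array per genotype), blastocysts (squares, 2 arrays per genotype) and implantation sites (triangles, 1 array per genotype). Ribosomal proteins lie at -0.88 in oocytes, -0.13 in blastocysts and 0.32 at the implantation site.

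Fitted over the 3 stages, lists of translation and chromatin genes were lower in the KO by small amounts with a preset correlation between genes. None held with an estimated correlation, and no single gene passed. At the implantation site their medians were above 0 as deposited, a sign that turned under some alternatives. With the stage in the model, 0 genes passed over the 8 arrays (limma), with 428 higher and 385 lower at an unadjusted p under 0.05. Among genes named without a pass (adjusted p = 0.707), the bradykinin receptor Bdkrb2 (log2 3.04, SE 0.81), the thyroxine carrier Ttr (2.74, SE 0.62) and Spink1 (2.61, SE 0.62) had higher values, and Chd9 (-2.20, SE 0.67), Kit (-2.17, SE 0.73) and Trim56 (-2.14, SE 0.77) lower ones. Chd9, Kit, Trim56 and Spink1 were below the brightest Bacillus control on all 4 blastocyst arrays, Bdkrb2 on both WT ones and Ttr on all but the first KO one, so the sizes are approximate (2.41, 1.71, 1.34, -1.11, -0.89 and -0.91 with a pseudocount, in the same order). Translation factors (median -0.25, adjusted p = 0.0122), epigenetic regulators (-0.28, adjusted p = 0.0321) and ribosome biogenesis genes (-0.15, adjusted p = 0.0470) were lower and immune and blood markers higher (0.63, adjusted p = 0.0321). None of these 4 held with an estimated correlation (adjusted p = 0.748 with an estimated correlation), and adjusted over the list alone 0 of their members passed. At the implantation site the medians of the 3 lower lists were above 0, at 0.11 (-0.02 after quantile normalization), 0.14 and 0.12. With the mean of all probe sets of a gene, those of epigenetic regulators and ribosome biogenesis turned below 0. That of ribosome biogenesis did so with probe sets without suffix too. None of the 4 passed without the first KO array or without the first WT array, where translation factors had -0.12 and ribosome biogenesis -0.08 (first WT array) and epigenetic regulators -0.14 (first KO array). Immune markers did not pass without the second KO array. Without the array labelled WT replicate 2 they did, at 0.39, while epigenetic regulators and ribosome biogenesis genes did not. Translation and ribosome biogenesis lists were prompted by the title here too. The list calls were 0 after quantile normalization and in the brightest 30% of probe sets, and 2 genes passed as higher without the implantation site arrays.

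From oocyte to blastocyst, oocyte-specific genes fell and genes of the first embryonic lineages and of protein synthesis rose. Oocyte-specific genes fell in 13 of 19 cases and rose in 1: the anti-apoptotic Bcl2l10 read 50910 and 84908 in oocytes and 16.1 to 85.0 in blastocysts, and Btg4, an adaptor of maternal transcript decay, 60246 and 77433 against 57.4 to 322. Outside that list, the oocyte genes Nlrp4a and Obox2 also fell. All 4 were below the brightest Bacillus controls in blastocysts (199 to 560), so no fold is given. Trophectoderm markers rose in 16 of 19 cases, with Eomes up 88.3-fold (log2 6.46, SE 0.48), the keratin Krt8 56.9-fold (5.83, SE 0.36) and Cdx2 50.4-fold. Inner cell mass markers rose in 11 of 16, including Nanog (56.2-fold), Tdgf1 (123-fold) and Dppa5a (105-fold). Ribosomal proteins rose in 43 of 44 cases (median log2 3.41; Rps10 6.06, SE 0.45), oxidative phosphorylation genes in 52 of 69, proteasome genes in 25 of 31 and translation factors in 27 of 42. Adjusted over the list alone these counts were 14 lower for oocyte genes and 16, 11, 43, 56, 27 and 28 higher. Calcoco2, Timd2, Crxos and Pramel7 rose from below the brightest Bacillus controls in oocytes to 38184 or more, 11285 or more, 21828 or more and 9181 or more. The folds of Eomes, Cdx2, Nanog and Tdgf1 rest on oocyte values below those controls too, as do Dppa5a and Rps10 on the KO array, and are approximate. Over all genes 3162 were higher and 2183 lower in blastocysts (limma, 4 blastocyst and 2 oocyte arrays). Scaling to a common median turned this split (2481 higher and 2517 lower, 49.6% higher against 59.2% as deposited) and moved the median of all genes by -0.35, after which 39 of 44 ribosomal genes still rose.

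At the implantation site, stromal and decidual genes of the uterus were higher and blastocyst lineage genes lower than in blastocysts. Uterine and decidual genes rose over blastocysts in 17 of 27 cases and fell in 1, among them the collagens Col3a1 (47005 and 37300 in the KO and WT) and Col1a1 (39380 and 38262), the stromal transcription factor Hand2 (18803 and 15722), the estrogen receptor Esr1 (9119 and 8021) and decidual Bmp2 (13285 and 8357). The immediate early gene Fos also rose (18318 and 31271). These 6 genes were below the brightest Bacillus control on 3 or all 4 blastocyst arrays, so no fold is given. Egr1 rose to 17405 and 20408 from 115 to 532, and Gja1 itself to 28105 and 44493, from 375 and 553 in KO and 9835 and 574 in WT blastocysts, both below the control on 2 of the 4 blastocyst arrays. Inner cell mass markers fell in 13 of 16 cases (Nanog, 4.94 and 10.6 at the implantation site against 1317 to 2467 in blastocysts) and trophectoderm markers in 15 of 19 (Cdx2, 111 and 31.1 against 3084 to 5980), all to the level of the Bacillus controls for these examples. Junction and adhesion genes fell in 16 of 25, led by Epcam (-6.03), and immune and blood markers rose in 5 of 13. Among these, S100a8 read 8258 and 1209 against 141 to 356, at control level on all blastocyst arrays but the first WT one (280 against 199). Adjusted over the list alone the counts were 18 higher for uterine, 15 and 16 lower for the embryonic, 16 lower for junction and 7 higher for immune genes. Over all genes 1798 were higher and 2353 lower than in blastocysts (limma, 2 and 4 arrays), or 2095 and 1732 with a common median (54.7% higher, against 43.3% as deposited), which moved the median of all genes by 0.31. Without the implantation site KO array the counts were 934 and 1101.

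**Figure D4:**
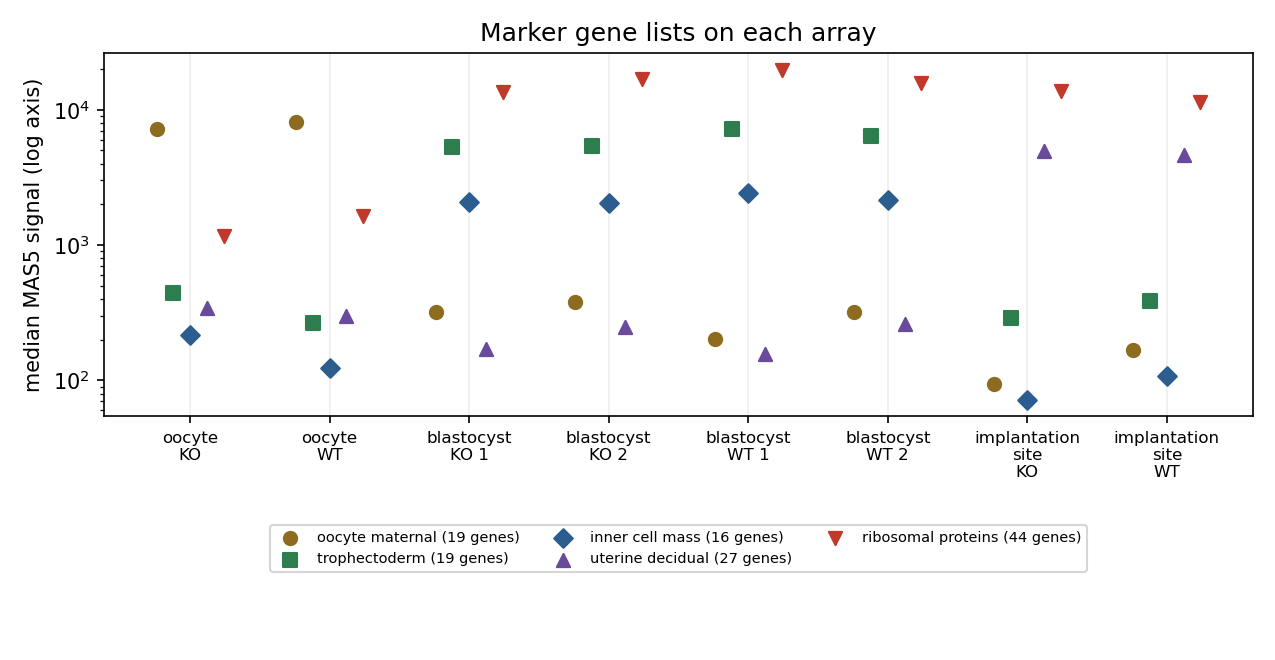
Median MAS5 signal (log axis) of the genes in each of 5 marker lists on each of the 8 arrays, with the number of genes measured in the legend. Oocyte-specific genes are brightest in oocytes, trophectoderm and inner cell mass markers in blastocysts and uterine and decidual genes at the implantation site, where inner cell mass markers lie at 72.1 and 108.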

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

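The brightness tests for the 12 genes and for the ribosomal list, the uterine tissue test, the comparison of signs between stages and the inclusion of probe sets shared with pseudogenes were chosen only after the result was seen.

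In several gene lists the KO minus WT median had the same sign in all 4 pairs of blastocyst arrays and the opposite sign in another stage. The difference was not tested, since the other stages have 1 array per genotype, and the values describe these arrays only. Genes as a whole changed sign with brightness as well. The 3044 brightest had a median of -0.31 in blastocysts and 0.16 at the implantation site, the dimmer 5873 genes 0.27 and -0.34. Random lists matched on brightness changed sign too from blastocysts to the implantation site for oxidative phosphorylation (-0.28 and 0.17) and epigenetic regulators (-0.21 and 0.08). The same held for cell cycle (-0.21 and 0.05), ribosome biogenesis (-0.20 and 0.02) and gastrulation genes (0.13 and -0.26). Those for primitive endoderm (-0.04 and -0.11) and mitochondrial ribosomal proteins (-0.12 and -0.05) did not. The differences between stages were not themselves set against matched lists. At the implantation site the median was above that of blastocysts, and the signs stayed opposite under both other scalings, for oxidative phosphorylation (difference 0.65), cell cycle genes (0.67), epigenetic regulators (0.65), primitive endoderm (0.62), ribosome biogenesis (0.41) and mitochondrial ribosomal proteins (0.32), and it was below it for gastrulation genes (-1.05). With the mean of all probe sets of a gene, however, the implantation site median turned below 0 for cell cycle genes, epigenetic regulators, primitive endoderm, ribosome biogenesis and mitochondrial ribosomal proteins, and with probe sets without suffix for cell cycle genes, primitive endoderm and ribosome biogenesis. After quantile normalization the implantation site median turned below 0 for translation factors (difference 0.50), stress response genes (0.63) and junction genes (0.51), and the blastocyst pairs were no longer of a single sign for early zygotic genes (-1.88, with the implantation site median at 0.13 with probe sets shared with pseudogenes included) and, with a common median as well, endothelial genes (-0.92). The implantation site median turned above 0 with a common median for cumulus and granulosa genes (-0.84) and, under quantile normalization as well, for trophoblast giant cell genes (-0.50). In oocytes, cumulus and granulosa genes were below the blastocyst median under all scalings (difference -1.40), although their oocyte median turned above 0 without the filter and with the mean of all probe sets. The oocyte medians above it turned below 0 after quantile normalization for inner cell mass markers (1.15), and under both other scalings for gap junction genes (1.03), primitive endoderm (0.56) and mitochondrial ribosomal proteins (0.45).

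Of the 12 genes higher in KO blastocysts, 9 had a lower value on the KO array of the implantation site, also not tested. These genes were chosen for their blastocyst rise, which makes up most of each difference between the stages. The 5873 dimmer genes as a whole were also lower on the implantation site KO array (median -0.34). Against the brightest Bacillus controls, Aloxe3 and the transcript with only a clone name were below on the implantation site KO array (131), Nova2 on both blastocyst WT arrays, the clone-named transcript on the first WT array (143 against 199) and Acap1 on the array labelled WT replicate 2 (189 against 219), so their sizes are approximate. The differences were -5.01 for Acap1, -5.28 for Nova2, -5.73 for Aloxe3, -4.06 for Smo, -4.23 for Aqp11, -4.04 for Gsc2, -3.94 for Zfp420 and -7.97 for the transcript with only a clone name. For Sec14l3 (-2.91) the implantation site value turned above 0 under both other scalings. In oocytes, by contrast, each of the 12 genes read higher on the KO array than on the WT array, also not tested. The readings ran from 372 against 361 for Acap1 to 1692 against 270 for Aqp11. The 5873 dimmer genes as a whole were higher on the oocyte KO array too (median 0.51). Ankzf1, Gsc2 and the clone-named transcript were below the brightest Bacillus control (132) on the oocyte WT array.

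The lower ribosomal values on the oocyte KO array do not rest on a brightness-dependent scale between the arrays as the whole cause, since after quantile normalization 0% of matched random lists still lay below the list median of -0.66. Shared or dim probe sets stay open: with probe sets without suffix, 16.61% of random lists lay below the median of -0.33 of 21 genes, and the same genes had -0.82 on the probe sets that represent them otherwise. With probe sets shared with pseudogenes included, 65 genes had a median of -1.04 and 0% of random lists lay below. The oocyte KO and WT arrays also differed in the 3' to 5' signal ratio, at 6.68 and 33.4 for Actb and 2.41 and 10.1 for Gapdh. Their median Bacillus control signals differed as well (123 and 37.9). An effect of the KO in oocytes could not be tested, with 1 array per genotype, and cannot be told apart from these differences between the arrays.

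On the array labelled WT replicate 2 the representing Gja1 probe set read close to the KO, although above the brightest control there (574 against 219). That control differed between arrays, at 560 on the second KO array, where Gja1 read 553. Other Gja1 probe sets on the array labelled WT replicate 2 lay on both sides of its control (190 and 166 below, 242, 430 and 855 above). The Gja1 signal raises the question of what the array labelled WT replicate 2 holds. Over the 316 genes called between the KO arrays and the first WT array, it lay at a median position of 0.395 between the KO mean (0) and the first WT array (1), with quartiles of 0.176 and 0.622, and 4 genes were called between the KO arrays and it. Whether it holds KO blastocysts cannot be told apart from ordinary spread between WT samples, since 35.1% of these genes lay under 0.25 and 38.6% over 0.5. These genes were also chosen because the first WT array lay far from the KO arrays, which draws the position of any other array towards the KO. Uterine tissue on the first WT array as the source of its Gja1 signal is argued against by 6 genes as bright as Gja1 at the implantation site. They were chosen to be far dimmer on the other blastocyst arrays, without regard to the first WT array. On the first WT array they reached a median of 0.165% of their implantation site signal, against 27.8% for Gja1. Among them, Col3a1 read 29.1 on that array and 47005 and 37300 at the implantation site. Over a wider set of 65 genes the share was 0.921%, against 0.953%, 0.948% and 0.884% on the other blastocyst arrays. The wider set was also chosen to be dim on those other arrays, which holds their shares down.

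Of the 12 genes higher in KO blastocysts, 11 were also called after quantile normalization. Their log2 differences were 2.49 or more, while the brightest 3044 genes had a median of -0.31 and the dimmer 5873 one of 0.27. A brightness scale of that size is far below the differences, so the calls could hardly be lost and this test decides little. That the called probe sets read transcripts other than the named gene stays open. Over the 100 genes with the smallest p among those that rose, the other probe sets of 37 genes had 0.0298 of the median difference of the representing ones, but among those that fell the ratio was also low, at 0.298 for 65 genes. A KO effect on these genes stays among the open explanations.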

How the results depend on the processing

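The inclusion of probe sets shared with pseudogenes was chosen only after the data were seen, and the cause of each change below was not tested unless stated. Over all alternatives, those printed below included, 189 values of main results gave the same outcome, 70 moved and 1 newly passed. Of other results 2445 gave the same outcome, 114 no longer passed and 11 newly passed. A further 282 moved by more than their spread or, for tests that passed in neither setting, changed sign. Another 6 changed direction, counted only where the untested value was at least 2-fold as deposited or a test passed in either setting. Smaller sign changes of untested values are not among these 6. Signal over background limits the unreplicated stages, where the dim side of 60.9% and 62.6% of the genes 2-fold apart lay at control level.

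In KO blastocysts the genes called higher and lower, 12 and 0 as deposited, were 74 and 10 with a common median, 23 higher with the pseudocount, 34 higher in the upper 30% of probe sets and 5 higher with probe sets without suffix, where fewer genes were tested. They were 0 and 0 with the mean of all probe sets of a gene or without the trend, and 91 and 1 with the replicate block, although nothing pairs the replicates. After quantile normalization 13 were higher and 1 lower. Leaving out 1 array gave 3 (first WT array) to 294 (the array labelled WT replicate 2) higher and 0 (first KO array) to 22 (the array labelled WT replicate 2) lower, with the lone array of a genotype assumed to vary like the others. Gja1 ranged from -4.43 (passing) to -0.33 when arrays were left out. With probe sets without suffix Aqp11 turned to -0.0213 and Ttc3 to -1.11. The 9 lower and 1 higher lists became 2 and 0 after quantile normalization, 2 and 0 in the upper 30% and 0 and 0 with an estimated correlation. The higher lists were 0 without the filter and 2 with probe sets without suffix. Leaving out 1 array gave 0 to 10 lists lower and 0 to 1 higher.

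Over the stages, 2 genes were higher without the implantation site pair, and leaving out 1 array gave 0 to 2 genes higher. The 3 lower lists and 1 higher list became 0 and 0 after quantile normalization, in the upper 30% and with an estimated correlation, and 5 were lower without the filter. Leaving out 1 blastocyst array gave 0 to 4 lower and 0 to 1 higher, and list tests without an oocyte or implantation site array were not run. Genes higher at the implantation site than in blastocysts were 1132 with the mean of all probe sets. Leaving out 1 array gave 934 to 1905 higher and 1101 to 2610 lower there.

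On the oocyte arrays, genes at least 2-fold higher and lower (2809 and 1444) were 1803 and 2211 after quantile normalization, 6151 and 2243 without the filter, where more genes were counted, and 1302 higher in the upper 30%. The lower genes were 2877 with a common median and 822 with the mean of all probe sets, where 80.5% of the genes 2-fold apart were higher. With probe sets without suffix Gja1 was -3.41, near background on both arrays, and Rab11fip4 turned from 4.57 to -0.0644. The ribosomal median of -0.88 was -1.29 with a common median, -0.49 with the mean of all probe sets and -0.33 with probe sets without suffix. At the implantation site the genes higher and lower (719 and 1862) were 1169 higher with a common median, 1164 lower after quantile normalization, 445 and 1197 with the pseudocount, 1879 and 4359 without the filter and 310 and 804 in the upper 30%. Kpnb1 turned to -0.33 with the mean of all probe sets and -0.71 with probe sets without suffix, and the early zygotic list to 0.13 with probe sets shared with pseudogenes. Between replicate blastocyst arrays, genes 2-fold apart (2055 in the KO, 2952 in the WT) were 4889 and 6683 without the filter and 960 and 1343 in the upper 30%.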

Other observations

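Beyond the lists that passed as a whole, single members of other lists differed in KO blastocysts when adjusted over the list alone, although none passed over all genes. Hand1, a transcription factor of trophoblast giant cells, read 711 and 1302 in the KO against 109 and 118 in the WT (log2 3.09, SE 0.58), where it was below the brightest Bacillus controls, as was Ttr on all blastocyst arrays but the first KO array. In the primitive endoderm list the endoderm products Ttr (3.69, SE 0.95) and Afp (1.31, SE 0.42) were higher, while the transcription factor Sox17 (-1.55, SE 0.41) and the laminin Lamb1 (-1.08, SE 0.30) were lower. The cell cycle inhibitor Cdkn1a (1.98, SE 0.45), the integrin Itgb5 (2.47, SE 0.51), the splicing factor U2af2 (2.36, SE 0.40) and Hhex (1.35, SE 0.38) were higher, and the imprinted gene Plagl1 was lower (-1.50, SE 0.33). As lists, none of these passed (camera): adjusted p was 0.433 for trophectoderm, 0.228 for trophoblast giant cells, 0.361 for primitive endoderm, 0.269 for p53 and apoptosis, 0.233 for junctions and adhesion, 0.422 for the spliceosome, 0.441 for gastrulation and 0.781 for imprinted genes. In 3 lists the signs disagreed: the median and the test were lower but the mean was 0.02 for primitive endoderm (median -0.43), 0.03 for tRNA synthetases (median -0.13, adjusted p = 0.504) and 0.02 for imprinted genes (median -0.09). The remaining lists had adjusted p of 0.575 (oocyte-specific), 0.265 (early zygotic), 0.216 (cumulus and granulosa), 0.531 (endothelial), 0.665 (glycolysis), 0.504 (cholesterol synthesis) and 0.575 (implantation signalling). Of the sex-linked list 2 genes were measured, so it was not tested as a list.

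Single chromatin, imprinted and gap junction genes passed between stages. From oocyte to blastocyst 9 of 22 epigenetic regulators were higher and 7 lower, with 4 and 2 of 16 imprinted and 2 and 1 of 7 gap junction genes. Between blastocysts and the implantation site the counts were 1 and 8, 6 and 3, and 2 and 2. The maintenance methyltransferase Dnmt1 read 20913 and 28451 in oocytes, fell to 1520 to 2495 in blastocysts (log2 -3.57, SE 0.31) and was 7.35-fold higher again at the implantation site. The de novo methyltransferase Dnmt3b was 5.26-fold higher in blastocysts than in oocytes and 15.4-fold lower at the implantation site. Tet2 rose from 21.2 and 120 in KO and WT oocytes to between 1996 and 2739 in blastocysts, and the histone deacetylase Hdac1 from 182 and 89.7 to between 2356 and 4319. Among imprinted genes Igf2r rose from 181 and 39.3 to between 2108 and 3539, and Cdkn1c fell from 2112 and 1616 to between 67.3 and 275. Phlda2 (17.1 and 13.2 at the implantation site, against 266 to 758) and Igf2 (113 and 39.2, against 722 to 1235) were lower than in blastocysts. The connexin gene Gjc1 fell from 727 and 1103 in oocytes to between 18.6 and 211 in blastocysts and was 5245 and 4710 at the implantation site, where Gjb5 was lower (88.6 and 29.3, against 252 to 1311). The low sides of these 8 genes were below the brightest Bacillus control, except on 1 WT array each for Cdkn1c and Gjc1, so no fold is given.

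Whether chance can be excluded for the KO effect over the stages was tested with other splits of the 8 arrays. Of 35 splits into groups of 4, 34 could be fitted, and 6 of the 34, the real one included, gave at least the real 813 genes at an unadjusted p under 0.05, the highest other having 1989. For gene lists 13 of the 34, the real one included, gave at least the real 4, with 10 as the highest other. Among the 12 splits balanced within stage, 2 gave as many genes and 5 as many lists, again with the real one counted. Several of these splits are not free of the genotype difference. With the stage in the model, the splits with 1343 genes and 7 lists each compare KO with WT blastocysts. That with 1989 genes keeps the genotypes of oocytes and blastocysts. Their counts are therefore no pure measure of chance, and chance is neither shown nor excluded for either count. The split with 1989 genes exchanges the 2 implantation site arrays. Correlations were taken across 11746 genes, which are not independent replicates. The KO difference at the implantation site had a correlation of -0.156 with that in oocytes and -0.158 with that in blastocysts. These shrank to -0.0667 and -0.0927 after quantile normalization. The oocyte difference had -0.105 with the mere difference between WT blastocyst replicates, so values of this size do not settle whether the stages differ in a shared way.

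A KO effect shared by oocytes and blastocysts was tested as a hypothesis by the correlation of their differences across the same genes. It was 0.157 as deposited and 0.0933 after quantile normalization, with a range of 0.0933 to 0.194 over the alternatives, against 0.000766 and -0.105 for the oocyte difference with the replicate differences of the KO and WT blastocysts. Values this small, near the absolute size of the correlation with the WT replicate difference (-0.105), do not settle whether such an effect exists.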
